A study of Mus musculus with 12 samples.

How the data were processed

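The data were small RNA counts from extracellular vesicles of cultured mouse bone marrow mesenchymal stem cells. The table held 12 libraries in 4 groups named DZ, aFM, NY and PLL, each with replicates A, B and C, and every library was assigned by its title. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

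The deposited values were whole-number counts per row, one column per library, with no normalization, as the values themselves show. Per the submitters' processing notes, the tools used were FastQC, STAR, StringTie and DESeq2 and the genome build was mm39, with no versions, roles or order. The miRNA caller, the miRBase release and the read filters are not given in the sources used here. Per the labels' protocols, the extraction text describes messenger RNA libraries, whereas the series' design text names a small RNA kit; the rows were mature miRNA names and predicted loci, as small RNA libraries give. The table had 3509 rows, of which 1978 carried mouse miRNA names and 1531 were predicted loci with a chromosome and a number. The predicted loci name no gene and were left out of library sizes and tests. They held 39.3% to 89.7% of a library's counts. The design had not foreseen them, and this choice was made before any test was run. A fit over all rows was added as an alternative, called below the fit with all rows or with predicted loci in the library sizes. Its filter, TMM factors, dispersions and adjustment also covered the predicted loci, with 712 of them and 141 annotated miRNAs tested. Its calls therefore differ by more than library size. Of the annotated rows, 501 had a count in some library.

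Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Rows were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 132 miRNAs holding at least 98.0% of each library's annotated counts. Libraries were scaled by TMM, and all 12 entered one quasi-likelihood fit with a term per group and no covariate. The 6 pairwise comparisons and a joint test of any group difference were two-sided, with Benjamini-Hochberg adjustment over the miRNAs tested and a threshold of 0.05. DZ was the common reference only; the labels do not call it a control. CPM values were computed from annotated counts and TMM-scaled library sizes. The SE of a log2 fold change was its size divided by the square root of the F statistic. Adjusted p-values in the text are from this fit unless another test is named.

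miRNAs were named by a rule that was set, like the 13 lists, before the data were examined. In each comparison with DZ these were up to 10 higher and 10 lower miRNAs of smallest p among those past the threshold whose libraries did not overlap, and in the other comparisons up to 5 and 5. Where fewer than 5 passed, those of smallest p filled up to 5. The 10 most abundant miRNAs and the list members of smallest p were named too. Each list is described in the comparison where its p was smallest. The lists were the let-7 family, the miR-17-92 paralogs, inflammation, osteogenesis-promoting, osteogenesis-restraining, mesenchymal, haematopoietic, epithelial, other tissues, the Dlk1-Dio3 cluster, p53-responsive, the Sfmbt2 cluster and pluripotency. The 8 lists with at least 3 tested members were tested with camera (preset correlation 0.01), adjusted over 48 tests, with an estimated correlation and fry beside it; fry compares no list with other miRNAs.

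The scripts were tested on simulated data drawn from the real means, library sizes and dispersions, with 40 changed miRNAs in each of 10 runs. For aFM against DZ, 9.25% of 2-fold, 73.2% of 4-fold and 95.2% of 16-fold changes were recovered. Each run simulated all 1978 annotated entries, of which 125 to 136 passed the filter and were tested. In 20 runs without any change the joint test made 0 calls. The common biological coefficient of variation was 40.4%.

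Total counts ran from 68647 to 214303 and annotated counts from 17607 to 60436 per library. A count of 0 in a library allows up to 3 counts, or 69.0 to 186 CPM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries of a group agreed within sampling noise in a chi-square test. Some annotated rows held identical counts in all libraries, among them miR-486a-5p with miR-486b-5p and miR-199a-3p with miR-199b-3p, so the same reads were counted more than once and such pairs are one measurement. List tests with the copies merged, list tests without miR-9-5p or a member of the other-tissues list, and an estimated correlation without PLL replicate A were added as alternatives.

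Replicate letters are shared by the groups. The correlation of same-letter deviations from the group means was above 0.1 for every letter only between NY and DZ (0.13 to 0.34), which met the criterion for pairing from the data; no label states a pairing. Alternatives covered the scaling, the filter, DESeq2 1.42.0, a replicate block, the most abundant miRNA left out, each library left out, a fold threshold and 2-group fits. Host genes came from GENCODE M21 on GRCm38; because the submitters' build differs, no coordinates are given. Figures were drawn with matplotlib.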

Results

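Extracellular vesicles are membrane particles released by cells that carry small RNA. Counts were examined for vesicles of mouse bone marrow mesenchymal stem cells, stromal cells that can form bone, cartilage and fat. The design text describes exposure for 48 h to 2 µg/ml of hydatid antigen preparations named ESPs, HCF and pLL. The question was how vesicle miRNAs differed between the groups. The labels give the groups DZ, aFM, NY and PLL with 3 libraries each and do not say what the first 3 names stand for, while PLL carries the name of pLL. The 3 preparations do not account for all 4 groups, and no label says which group, if any, was unstimulated. Library totals ranged from 68647 to 214303 counts, and annotated miRNAs took 17.5% ± 6.23 of them in DZ, 15.4% ± 4.61 in aFM, 23.7% ± 6.23 in NY and 43.9% ± 15.9 in PLL (SD, n = 3). The difference between PLL and DZ had an exact permutation p = 0.1, the smallest that 3 against 3 allows.

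**Figure D1:**
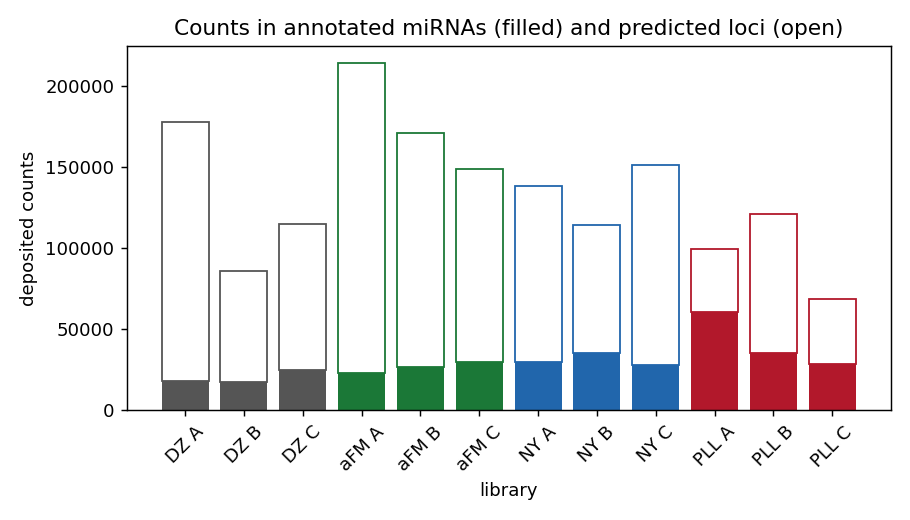
Deposited counts (vertical axis) for each of the 12 libraries, with filled bars for annotated miRNAs and open bars for predicted loci. PLL replicate A had 60436 annotated counts and DZ replicate B had 17607.

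Averaged over the 12 libraries, the 10 most abundant miRNAs took 57.3% of annotated counts, called the abundance share here. They were miR-21a-5p (9.65%), miR-143-3p (6.89%), miR-148a-3p (6.81%), let-7c-5p (5.46%), miR-486a-5p and its identical copy miR-486b-5p (5.42% each), let-7i-5p (5.10%), miR-26a-5p (4.80%), let-7b-5p (3.95%) and miR-9-5p (3.80%). These averages cover unequal groups: miR-9-5p took 0.0311% ± 0.0243 in DZ, 0.749% ± 0.112 in NY, 3.52% ± 0.155 in aFM and 10.9% ± 4.03 in PLL (SD, n = 3), where miR-21a-5p took 8.80% ± 2.50. miR-148a-3p took 7.44% ± 4.58 in PLL (SD, n = 3), where replicate A held 176869 CPM against 45777 and 41891 in the others. Exact permutation tests of the abundance share between groups gave p of 0.3 to 0.8 and adjusted p of 0.75 to 0.8 over 6 comparisons. With 3 against 3 the smallest exact p is 0.1, so no pair could have passed and equal shares are not shown. Of 132 miRNAs tested, 16 differed among the groups in the joint test, and miR-9-5p led them. That count was 9 without aFM replicate A or B and 10 without NY replicate A.

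miR-9-5p, best known from the nervous system and also induced in myeloid cells by inflammatory signals, spanned the widest range. It stood at 331 ± 257 CPM in DZ, 7623 ± 626 in NY, 33896 ± 3044 in aFM and 109434 ± 20094 in PLL (SD, n = 3). All 6 pairwise differences passed the threshold. Of these, NY against aFM did not pass without NY replicate A, B or C (adjusted p = 0.102, 0.101 and 0.0667), and PLL against aFM did not pass without aFM replicate A, B or C or PLL replicate C (adjusted p = 0.0759, 0.0948, 0.126 and 0.0676). Against DZ the log2 fold changes were 4.61 ± 0.50 (SE; adjusted p = 0.000129) in NY, 6.76 ± 0.54 (adjusted p = 3.84e-06) in aFM and 8.45 ± 0.57 (adjusted p = 5.79e-07) in PLL. In GRCm38 its genes are Mir9-1, Mir9-2 and Mir9-3, each within a long noncoding RNA gene on the same strand. The other arm, miR-9-3p, had 2 counts in all libraries together, both in NY.

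**Figure D2:**
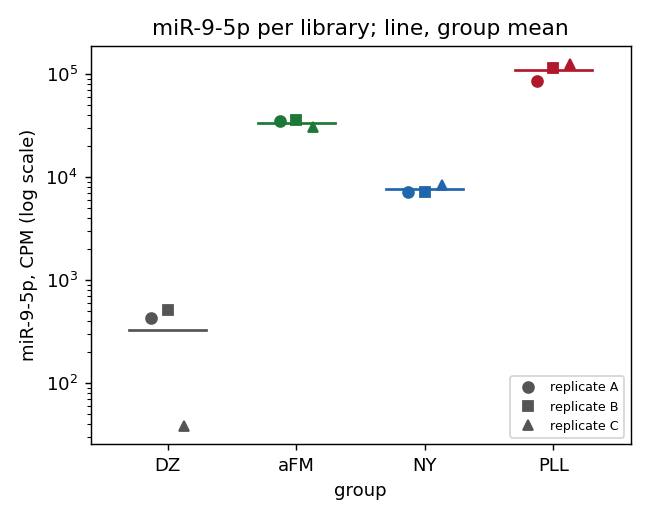
miR-9-5p in CPM on a log scale (vertical axis) by group, with circles, squares and triangles for replicates A, B and C and a line for the group mean. Group means ran from 331 in DZ to 109434 in PLL, and no libraries of different groups overlapped.

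The first comparison asked how aFM differed from DZ. In aFM, 12 miRNAs were higher and 13 lower. Apart from miR-9-5p, the higher ones of smallest p were miR-126a-3p, an endothelial miRNA lying within Egfl7, at 4886 ± 273 against 804 ± 572 CPM (log2 fold change 2.63 ± 0.46, adjusted p = 0.0047), and miR-3960, linked to osteoblast differentiation, at 4531 ± 662 against 267 ± 179 CPM (4.15 ± 0.74, adjusted p = 0.0047). miR-5099, miR-151-3p, which lies in an intron of Ptk2, and miR-378c were higher too, with log2 fold changes of 3.09, 0.82 and 2.58. Lower in aFM were miR-16-2-3p (log2 fold change -1.80), miR-146a-5p, a brake on NF-κB signalling (538 ± 390 against 2209 ± 921 CPM), miR-185-5p (-1.30), miR-21a-5p (-0.58), miR-484 (-1.88), the hypoxia-induced miR-210-3p (-2.65) and miR-191-5p (-0.80), with adjusted p from 0.0252 to 0.0415. The smooth muscle miRNA miR-145a-5p had 2 counts in aFM and 28 in DZ, a ratio of 19.5 (95% counting interval 4.91 to 169). The interval pools the libraries of a group, and the DZ libraries held 124, 867 and 423 CPM. The more abundant other arm, miR-145a-3p, differed far less, with 1114, 710 and 829 CPM in aFM against 1734, 1792 and 1309 in DZ. miR-486a-5p, an erythroid miRNA within Ank1, stood at 37181 ± 1722 CPM in aFM against 78296 ± 31299 in DZ (-1.07 ± 0.33, adjusted p = 0.0415).

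miRNAs of the imprinted Dlk1-Dio3 cluster were higher in aFM. Of 5 tested members, 4 were higher than in DZ and 0 lower, and all 5 when adjusted over the list alone. miR-127-3p stood at 2069 ± 408 against 329 ± 310 CPM (log2 fold change 2.57 ± 0.75, adjusted p = 0.0415) and miR-381-3p at 699 ± 136 against 83.5 ± 86.9 CPM (3.00 ± 0.91, adjusted p = 0.0415). miR-411-5p had 78 counts in aFM and 1 in DZ, a ratio of 56.1 (95% counting interval 9.77 to 2242), and miR-409-3p had 97 and 3, a ratio of 23.2 (7.72 to 115). The camera list test gave adjusted p = 0.000169, and adjusted p = 0.0284 with an estimated correlation. The fry test, which asks whether the members move on balance one way, gave adjusted p = 4.43e-05. Fry also passed for this list, upward, in NY against DZ (adjusted p = 0.00812) and PLL against DZ (adjusted p = 0.0109), where camera did not (adjusted p = 0.144 and 0.4) and 0 of 5 members were called. The same list was lower in NY than in aFM (1 of 5 members called, 3 when adjusted over the list alone) and lower in PLL than in aFM (1 of 5, and 4 when adjusted over the list alone), both with camera adjusted p = 0.000234, and adjusted p = 0.0284 with an estimated correlation. The difference between PLL and aFM did not pass without PLL replicate C (adjusted p = 0.129) or without aFM replicate C (adjusted p = 0.053). Lists were not tested in the fit over all rows, where the median annotated miRNA stood at 2.13 in PLL against aFM. The median of this list was -1.72 in the main fit, so its direction there under that scaling is not known. Its member miR-411-5p kept a log2 fold change of -3.45 or lower under all alternatives. Without PLL replicate A all 3 differences of this list kept the camera call, but with an estimated correlation none did (adjusted p = 0.102 each). These 3 of 48 camera tests passed, and 13 of 48 fry tests, of which 5 were for this list.

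**Figure D3:**
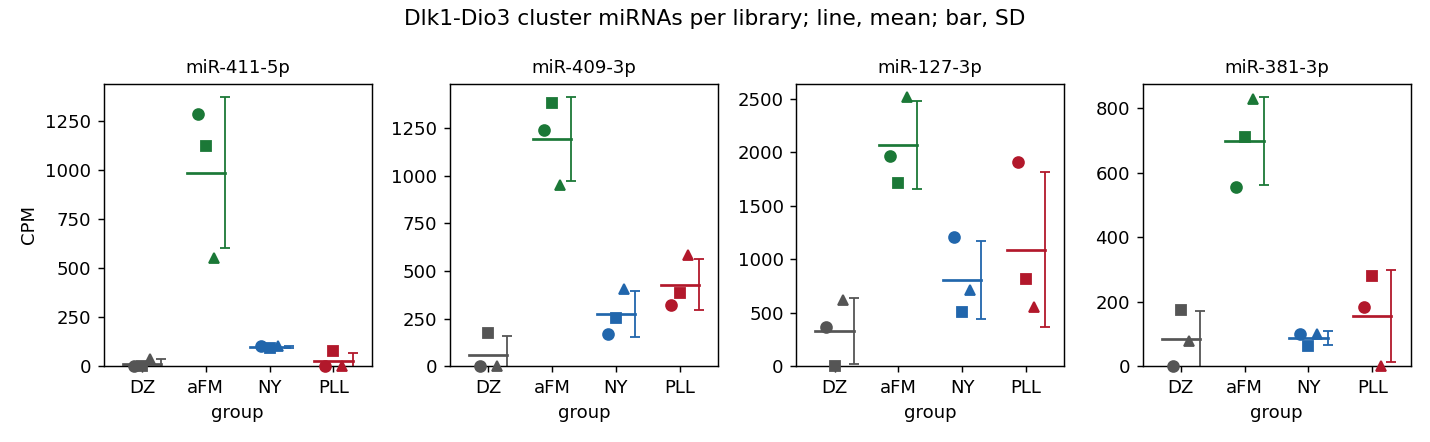
CPM (vertical axis) of 4 Dlk1-Dio3 cluster miRNAs by group, with circles, squares and triangles for replicates A, B and C, a line for the mean and a bar for the SD, cut at 0. The mean of miR-127-3p was 2069 in aFM and 329 in DZ.

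The count of 25 calls for aFM against DZ fell by more than 1.5 times without any library except PLL replicate A, without which it was 26. It was 8, 6 and 15 without DZ replicates A, B and C, 5, 5 and 6 without aFM replicates A, B and C, 9, 8 and 11 without NY replicates A, B and C, and 16 and 12 without PLL replicates B and C. The split also moved with the scaling, from 12 higher and 13 lower to 12 and 4 with RLE factors. It was 8 and 15 with upper quartile factors and 7 and 1 with library totals. In the fit over all rows, where filter, dispersions and adjustment changed too, it was 4 and 3. Of 20 called miRNAs named for this comparison, miR-9-5p, miR-126a-3p, miR-3960, miR-411-5p and miR-409-3p passed whichever library was left out. Each of the other 15 was lost when any of 4 to 12 libraries was left out singly, with adjusted p up to 0.181. Identical copies such as miR-486a-5p and miR-486b-5p count separately here; with copies merged, 9 miRNAs were higher and 10 lower.

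In NY against DZ only miR-9-5p passed, and 19 miRNAs had an unadjusted p under 0.05. DESeq2 called 6. The next 4 by p did not pass. They were miR-192-5p (log2 fold change -1.86 ± 0.56), miR-5124a (-2.04 ± 0.64), the muscle miRNA miR-206-3p (2.49 ± 0.81) and miR-378c (2.23 ± 0.74), each with adjusted p = 0.246. DZ replicate C held 8084 CPM of miR-192-5p against 2230 and 1503 in the other DZ libraries. Leaving out DZ replicate A, B or C gave 2 calls each.

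In PLL against DZ, 1 miRNA was higher and 4 were lower. Apart from miR-9-5p, miR-143-3p, abundant in mesenchymal and smooth muscle cells, stood at 37501 ± 7799 against 82133 ± 6217 CPM (log2 fold change -1.13 ± 0.17, adjusted p = 0.00202). let-7c-5p was 38390 ± 2478 against 64065 ± 2457 CPM (-0.74 ± 0.14, adjusted p = 0.00734) and let-7b-5p 25203 ± 1389 against 41010 ± 3979 CPM (-0.70 ± 0.15, adjusted p = 0.0182). Both let-7 genes lie in Lncppara in GRCm38, and let-7c has another copy in Mir99ahg. miR-676-3p, within an intron of Eda, was lower as well (-3.68 ± 0.84, adjusted p = 0.0246). The fall of miR-143-3p, let-7b-5p and let-7c-5p is relative to the other annotated miRNAs. When predicted loci entered the library sizes, their log2 fold changes were 0.24, 0.79 and 0.68 and did not pass, and the median annotated miRNA stood at 1.73. Without DZ replicates B and C and PLL replicates B and C in turn, the count was 8, 11, 17 and 9. With library totals it was 1 higher and 1 lower, and with predicted loci in the library sizes 58 and 0. miR-676-3p did not pass without DZ replicate A, DZ replicate B or NY replicate C (adjusted p = 0.0514, 0.0692 and 0.0548). PLL replicate A differed from the other PLL libraries in several abundant miRNAs, among them miR-140-3p, a cartilage miRNA, with 101387 CPM against 5486 and 5204.

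**Figure D4:**
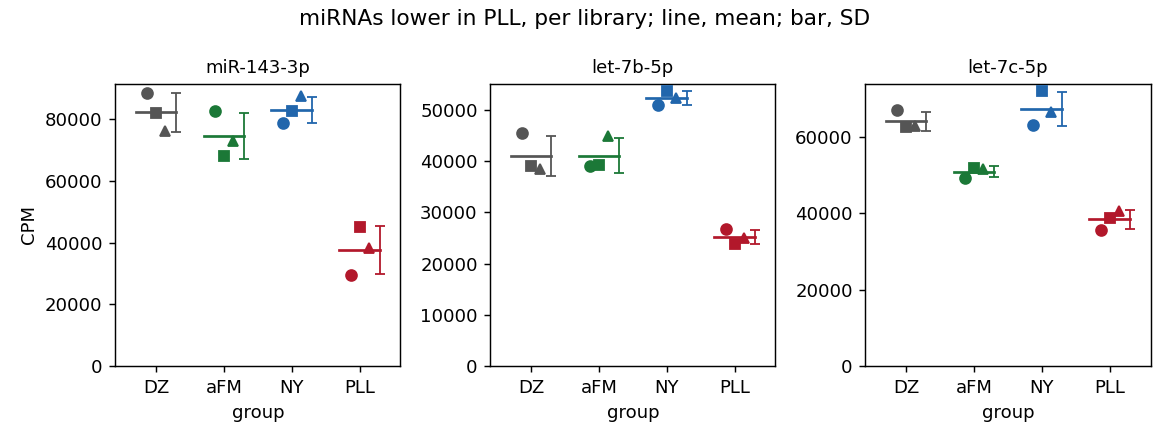
CPM (vertical axis) of miR-143-3p, let-7b-5p and let-7c-5p by group, with circles, squares and triangles for replicates A, B and C, a line for the mean and a bar for the SD. miR-143-3p averaged 37501 in PLL and 82133 in DZ. With predicted loci in the library sizes its log2 fold change had the opposite sign (0.24) and did not pass.

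The remaining comparisons set aFM, NY and PLL against each other. NY and aFM differed in 5 miRNAs. miR-21a-5p was higher in NY (120630 ± 12411 against 72002 ± 6747 CPM, log2 fold change 0.74 ± 0.16, adjusted p = 0.027). Lower were miR-126a-3p (-3.06 ± 0.46, adjusted p = 0.00346), miR-9-5p (-2.15 ± 0.41, adjusted p = 0.0129), miR-411-5p (-3.25 ± 0.73, adjusted p = 0.027) and miR-3960 (-2.68 ± 0.65, adjusted p = 0.0357). The count was 9, 8 and 9 without DZ replicates A, B and C, 2 without any aFM library, 1 without any NY library and 12 without PLL replicate A. With RLE factors, upper quartile factors or library totals it was 0 higher and 4 lower, and with predicted loci in the library sizes 7 and 2. Only miR-126a-3p among these 5 passed whichever library was left out. Without each aFM and each NY library in turn, miR-21a-5p, miR-411-5p and miR-3960 did not pass, with adjusted p up to 0.216, 0.155 and 0.149, and miR-21a-5p did not pass without PLL replicate B or C either (adjusted p = 0.0799 and 0.0522).

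PLL and aFM differed in 12 miRNAs, 8 higher and 4 lower in PLL. The higher ones included miR-221-3p (log2 fold change 1.14 ± 0.25), miR-23a-3p (2.26 ± 0.49), miR-9-5p (1.69 ± 0.40), miR-146b-5p, a paralog of miR-146a-5p that also restrains NF-κB signalling (2.10 ± 0.50), and miR-191-5p (0.92 ± 0.24), with adjusted p from 0.014 to 0.0317. Lower were miR-3960 (-4.81 ± 0.74, adjusted p = 0.00401), miR-143-3p (-0.99 ± 0.17, adjusted p = 0.00442) and let-7b-5p (-0.71 ± 0.15, adjusted p = 0.014). miR-411-5p had 3 counts in PLL and 78 in aFM, a ratio of 35.7 (95% counting interval 11.8 to 177). The count was 20 without DZ replicate B and 5, 4 and 4 without aFM replicates A, B and C. With RLE factors it was 4 higher and 4 lower, and with predicted loci in the library sizes 82 and 2, where miR-143-3p and let-7b-5p had log2 fold changes of 0.80 and 1.15. Of 9 named miRNAs, miR-3960, miR-411-5p and miR-143-3p passed whichever library was left out. let-7b-5p did not pass without aFM replicate C (adjusted p = 0.0687). miR-23a-3p did not pass without aFM replicate B or C (adjusted p up to 0.0891). Its PLL libraries varied widely, at 2951 ± 2154 CPM against 620 ± 141 in aFM (SD, n = 3). Across alternatives its log2 fold change ran from 1.41 to 4.42. miR-9-5p and miR-146b-5p did not pass without any aFM library or PLL replicate C (up to 0.126 and 0.137). miR-221-3p did not pass without any aFM library or PLL replicate B or C (up to 0.134). miR-191-5p did not pass without 9 of the libraries, namely any aFM library, PLL replicates B and C, DZ replicates A and C and NY replicates A and C (up to 0.184).

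PLL and NY differed in 9 miRNAs. Higher in PLL were miR-9-5p (log2 fold change 3.84 ± 0.44, adjusted p = 0.000189), miR-126a-3p (1.76 ± 0.45, adjusted p = 0.0356), miR-146b-5p (1.84 ± 0.49, adjusted p = 0.0404) and miR-1895, with 113 counts in PLL and 3 in NY, a ratio of 30.2 (95% counting interval 10.1 to 149). Lower were let-7b-5p (-1.05 ± 0.15), miR-143-3p (-1.14 ± 0.17), let-7c-5p (-0.81 ± 0.14), miR-615-3p, within Hoxc5 (-1.64 ± 0.38), and miR-206-3p (-3.15 ± 0.81), with adjusted p from 0.00101 to 0.0356. The count was 5 without NY replicate B. With predicted loci in the library sizes it was 34 higher and 0 lower, and let-7b-5p, let-7c-5p and miR-143-3p had log2 fold changes of 0.24, 0.44 and 0.050. miR-126a-3p did not pass without NY replicate A or B, PLL replicate B or C or any aFM library (adjusted p up to 0.189), and miR-146b-5p without any NY or aFM library or PLL replicate A or C (up to 0.204). miR-206-3p did not pass without any NY or PLL library (up to 0.121), and miR-615-3p without NY replicate B or C (up to 0.0664).

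The other lists did not pass the camera test. With fry, which compares no list with other miRNAs, the inflammation list passed upward in aFM, NY and PLL against DZ (adjusted p = 0.00798, 0.00125 and 4.43e-05), PLL against aFM (0.000795) and PLL against NY (0.00125). Without miR-9-5p these fry values were 0.0243 in the opposite direction, 0.801, 0.333, 0.00789 and 0.573, and NY against aFM went from 0.831 to 0.0112. The other-tissues list passed fry upward in aFM against DZ (0.00599) and downward in NY and PLL against aFM (0.0109 and 0.0107), with 1, 1 and 0 of its 4 members called. Its mean and median log2 fold changes in aFM against DZ were 0.80 and 0.32, and camera with an estimated correlation gave adjusted p = 0.328 in all 3. Without miR-126a-3p, the called member, fry gave adjusted p = 0.316, 0.891 and 0.214 in these comparisons, and without miR-128-3p it gave 0.0661 in PLL against aFM. Without miR-122-5p, high in DZ replicate C, all 3 passed, as did NY against DZ (0.00559) and PLL against DZ (0.0184), and without miR-206-3p PLL against NY passed too (0.0126). In PLL against DZ the inflammation list (7 tested, 1 higher, 2 when adjusted over the list alone) had adjusted p = 0.119; its member miR-146b-5p had a log2 fold change of 1.66 ± 0.50 (adjusted p = 0.0647). Without PLL replicate A the inflammation list passed in PLL against DZ (adjusted p = 0.0127) and in NY against DZ (adjusted p = 0.048) with the preset correlation, but with an estimated correlation neither passed (adjusted p = 0.149 and 0.237, and 0.315 in both with all libraries). Without PLL replicate A and miR-9-5p, the preset correlation gave adjusted p = 0.926 in both. With all libraries its called member in both comparisons was miR-9-5p, and its mean and median log2 fold changes were 1.42 and 0.088 in PLL against DZ and 0.63 and 0.16 in NY against DZ. With all libraries and miR-9-5p left out of the list, the camera p before adjustment was 0.725 in PLL against DZ and 0.867 in NY against DZ. The haematopoietic list held miR-486a-5p and miR-486b-5p, the same reads counted under both names, so its 4 tested members were 3 measurements. With the copies merged, 0 were called in PLL against DZ, 1 was lower when adjusted over the list alone (miR-486a-5p, -1.02 ± 0.33 before merging, and 0.50 with predicted loci in the library sizes), and the list had adjusted p = 0.377 (0.169 with the copies kept apart). In aFM against DZ 2 of the 3 were lower, miR-486b-5p and miR-142a-5p, also 2 when adjusted over the list alone, and the list had adjusted p = 0.352 (0.169 with the copies kept apart). The other-tissues list (4 tested, 0 called, 1 lower when adjusted over the list alone) had adjusted p = 0.169 in PLL against aFM, where miR-126a-3p had -1.29 ± 0.42 and miR-128-3p -0.55 ± 0.25, and 0.54 and 1.37 with predicted loci in the library sizes. The osteogenesis-restraining list (8 tested, 0 called, 0 when adjusted over the list alone) had adjusted p = 0.521 in NY against aFM, with miR-206-3p at 2.55 ± 0.79 and miR-23a-3p at 0.92 ± 0.49. The osteogenesis-promoting list (5 tested, 0 called, 0 when adjusted over the list alone) had adjusted p = 0.681 in PLL against NY, with miR-3960 at -2.13 ± 0.73 and miR-26a-5p at 0.52 ± 0.28; its mean was -0.37 and its median 0.083. The let-7 family (9 tested, 1 lower, 1 when adjusted over the list alone) had adjusted p = 0.575 in PLL against aFM, and the mesenchymal list (11 tested, 0 called, 0 when adjusted over the list alone) 0.972 in NY against DZ, with miR-145a-5p at -2.07 ± 0.95, miR-145a-3p at -0.52 ± 0.35, a mean of -0.12 and a median of 0.032. Of lists too small to test as sets, the miR-17-92 paralogs and the p53-responsive list had 2 tested members each and the epithelial and Sfmbt2 lists 1 each, with 0 calls in aFM against DZ. No pluripotency member had a count.

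Fold changes against DZ correlated across miRNAs, which are not independent replicates and share the DZ libraries. Pearson's r was 0.64 between aFM and NY, 0.57 between aFM and PLL and 0.56 between NY and PLL, where simulated unchanged groups gave 0.51, 0.54 and 0.52. Spearman's rho was 0.57, 0.54 and 0.44. The central 95% of simulated r ran from 0.34 to 0.64, 0.36 to 0.70 and 0.34 to 0.66, and the r of aFM with PLL and of NY with PLL lay within theirs. The share of miRNAs with the same sign was 66.7%, 67.4% and 65.9%, against 67.4%, 68.0% and 67.6% in the simulation. Without miR-9-5p, r was 0.56, 0.45 and 0.42, and the values 0.45 and 0.42 lay below the simulated 0.54 and 0.52. With miR-9-5p included, the covariance exceeded the simulated one by 0.66, 0.82 and 0.50. How much of this excess came from miR-9-5p was not computed. Its log2 fold changes were 6.76 in aFM, 4.61 in NY and 8.45 in PLL, so the excess need not reflect many miRNAs. With 3 DZ libraries the reference could not be split, and part of the excess may come from it. The only miRNA called higher in more than 1 comparison with DZ was miR-9-5p, where independent lists would share 0.0909 miRNAs for aFM with NY or PLL and 0.00758 for NY with PLL, and 0 were called lower in more than 1.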

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

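All tests of explanations in this part were chosen after the values were seen; the splits of the samples were planned.

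The predicted loci, which were left out of the tests of annotated miRNAs, held a signal far above the limit that a count of 0 allows. They took between 39.3% and 89.7% of a library's counts, and 1411 loci had more than 3 counts in total. In a fit over all rows, 712 predicted loci were tested in each comparison. Those called numbered 88 for aFM against DZ, 122 for NY against DZ and 243 for PLL against DZ. They numbered 204 for NY against aFM, 227 for PLL against aFM and 184 for PLL against NY. Of 141 annotated miRNAs tested beside them, 7, 1, 58, 9, 84 and 34 were called in the same order.

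The step-wise difference of miR-9-5p was set against technical sources. If the reads came from neural tissue, other neural miRNAs should follow; the neural list reached 2.66% of the PLL count of miR-9-5p, which fell between the bounds set for it and gave no verdict, with 280 of its 324 counts from miR-128-3p. A test added after that outcome found miR-124-3p, abundant in neurons, at 0.082% of miR-9-5p, which argues against neurons as the source. It cannot decide on neural cells that hold little miR-124-3p. Carry-over from PLL libraries would keep other PLL-rich loci in aFM. The median over 7 such loci was 0% of the PLL count against 22.8% for miR-9-5p, which argues against it there. In NY the median was 68.2% against 5.68%, with 2 of the 7 more than 2-fold under the miR-9-5p ratio. That gave no verdict by the bounds set. Carry-over at 1 rate would, however, leave every PLL-rich locus at or above that ratio in NY. The locus chr4_55378 had 5285 counts in PLL and 28 in NY, and chr9_81497 had 749 and 0. These values argue against carry-over at 1 rate into NY. Reads from another organism that carries miR-9 may be a source and cannot be told apart from the mouse miRNA here: 0 conserved miRNAs were called higher in PLL, but only 1 could be tested, and a response of the cells to the stimulus stays open too.

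PLL replicate A held 101387 CPM of miR-140-3p, a cartilage miRNA, against 5486 and 5204 in the other PLL libraries. A library of another group under a PLL label is argued against, since its miR-9-5p was 2.40 times the highest library outside PLL. A larger share of mesenchymal RNA may contribute and could not be settled, with 6 of 11 tested mesenchymal members higher than in both other PLL libraries, against 36.4% of all tested miRNAs. These 11 include the identical miR-199a-3p and miR-199b-3p; with copies counted once it was 5 of 10, against 33.9%.

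DZ replicate C held 38726 CPM of the hepatocyte miRNA miR-122-5p against 1920 and 4393 in the other DZ libraries. RNA of liver or serum is a possible explanation that the counts do not settle. In DZ replicate C, 3 of 4 tested liver-list members were higher than in both other DZ libraries, against 22.0% of all tested miRNAs. These include miR-122-5p, which raised the question, and miR-192-5p, already seen to be high there and also on the p53-responsive list. Of the others, miR-148a-3p was higher (62902 against 46025 and 45726 CPM) and miR-101a-3p was not (1309 against 867 and 1445 CPM). The aFM libraries held 13723 to 15949 CPM of miR-122-5p.

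Other splits of the libraries were fitted as well. For the joint test, 1 of 100 splits, the real one, gave as many calls (16, highest other 2). That is the smallest share that 100 splits allow. It concerns only how these libraries were grouped, and cannot cover variation between cultures, since the replicates may be technical. With 10 splits a pairwise comparison cannot reach a share under 0.05. The real and highest other counts were 25 and 0 for aFM against DZ, 5 and 1 for PLL against DZ, 5 and 1 for NY against aFM, 12 and 0 for PLL against aFM and 9 and 0 for PLL against NY. For NY against DZ they were 1 and 2, and 3 of the 10 splits gave at least as many. The splits took no account of the replicate letter, though NY and DZ met the pairing criterion.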

How the results depend on the processing

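The fit over all rows, the merging of identical rows in fits and lists, the omission of PLL replicate A and DZ replicate C together, the robust fit, the 2-group block, the omission of miR-9-5p or other-tissues members from lists, that of miR-9-5p from correlations, and the estimated list correlation without PLL A were chosen after seeing the data. Of 930 values of called named miRNAs under alternatives, 639 kept direction and side of the threshold, 283 kept direction only and 8 reversed. miR-9-5p passed against DZ in all 3 comparisons under all 19 alternatives, with a largest adjusted p of 0.000551. Counts of calls moved more, and except where stated the cause was not tested. In the joint test 16 became 38 with no filter, 28 with the strict filter, 36 with DESeq2, 79 with all rows and 41 without PLL A and DZ C. For aFM against DZ 25 became 16 with RLE, 8 with library totals, 15 with no filter, 9 with the strict filter, 10 with the replicate block and 7 with all rows. For NY against DZ 1 became 7 with no filter, 3 with the strict filter, 6 with DESeq2 and 2 without PLL A and DZ C. For PLL against DZ 5 became 2 with library totals, 17 with no filter, 8 with the strict filter, 20 with DESeq2, 3 with the replicate block, 58 with all rows, 9 without PLL A and DZ C, 3 with a log2 threshold of 1 and 1 in a 2-group fit. For NY against aFM 5 became 11 with no filter, 15 with DESeq2, 2 with the replicate block, 9 with all rows, 30 without PLL A and DZ C and 29 in a 2-group fit. For PLL against aFM 12 became 25 with DESeq2 and 84 with all rows, and for PLL against NY 9 became 16 with no filter and 34 with all rows. Leaving out 1 library gave 9 to 23, 5 to 26, 1 to 2, 4 to 17, 1 to 12, 4 to 20 and 5 to 11 calls in the same order, 2 to 5 list calls, and an abundance share of 56.7% to 58.2% for the top 10, which was 9.65% for the top 1 and 92.2% for the top 50 by construction.

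With all rows, annotated miRNAs stood higher in PLL (median log2 fold change 1.73 against DZ, 2.13 against aFM and 1.49 against NY). The PLL group had the highest mean annotated share, 43.9%, though PLL replicate B (29.2%) lay below NY replicate B (30.6%). TMM factors of that fit also rested on predicted loci, and what set the size of the shift was not tested. That fit changed the sign of the log2 fold changes of miR-143-3p (0.24, 0.80 and 0.050), let-7b-5p (0.79, 1.15 and 0.24) and let-7c-5p (0.68, 1.43 and 0.44) in these comparisons. Against DZ none of the 3 passed there. Nor did miR-143-3p against aFM or NY (edgeR adjusted p = 0.187 and 0.952) or let-7b-5p against NY (0.749). A value such as 0.050 is close to no difference. The same fit changed the sign of miR-486a-5p and miR-486b-5p against DZ (0.50) and of miR-126a-3p (0.54) and miR-128-3p (1.37) against aFM. Other scalings of annotated counts moved the median of aFM against DZ from -0.14 to -0.32 (upper quartile) and -0.022 (library totals), NY against DZ from 0.022 to -0.22 (upper quartile), PLL against DZ from 0.22 to 0.076 (upper quartile), NY against aFM from 0.18 to 0.063 (RLE), PLL against aFM from 0.31 to 0.16 (library totals) and PLL against NY from 0.17 to 0.27 (upper quartile). Fold-change correlations were 0.45 (aFM, NY) and 0.47 (NY, PLL) with the strict filter and 0.56, 0.45 and 0.42 without miR-9-5p; leaving out 1 library gave 0.49 to 0.68, 0.46 to 0.63 and 0.42 to 0.59.

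Replicate letters met the pairing criterion only for NY against DZ, where the replicate block gave 1 call, as did a block in a 2-group fit, so it changed no call there. For aFM against DZ the 3 aFM libraries each correlated best with their own letter in DZ, a hint from the data and not from the design. At the depth, spread and number of these libraries, the simulation for PLL against DZ recovered 8% of 2-fold changes; depth was not varied on its own.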

Other observations

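The tests in this part were chosen after the values were seen.

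The Dlk1-Dio3 cluster had 21 further members with too few counts to be tested one by one. Their summed level was 514 ± 262 CPM in DZ, 1462 ± 356 in aFM, 658 ± 77.9 in NY and 1699 ± 271 in PLL (SD, n = 3). A hypothesis is that the cluster as a whole may be higher in aFM than in DZ. The lowest aFM library was 1.54 times the highest DZ library over these members, as that hypothesis predicts. The exact permutation p of 0.1 is the smallest 3 against 3 allows. Every PLL library also lay above every DZ library (lowest 1480 against highest 809 CPM, exact permutation p = 0.1). These members therefore did not set aFM apart from PLL. In PLL the sum rested partly on miR-341-3p, with 63 counts in PLL, 1 in aFM and 0 in DZ and NY; without it PLL stood at 1175 ± 337 CPM and aFM at 1447 ± 370.

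Some predicted loci differed widely between groups. In the edgeR fit over all rows, chr10_10531 was higher in aFM than in DZ (adjusted p = 0.00384), with 43241 counts in aFM, 1027 in DZ (0.327% ± 0.325 of all counts, SD, n = 3), 262 in NY and 347 in PLL. chr11_14936 was higher in PLL than in DZ (adjusted p = 4.21e-06), with 5077 counts against 63, and 45 in NY.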
